A study of Mus musculus with 12 samples.

How the data were processed

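Total kidney RNA of female mice was labelled with biotin and hybridised to 12 Affymetrix whole-transcript arrays. The labels put 4 arrays in each of 3 groups, which are wild-type mice injected with recombinant FGF23, wild-type mice injected with saline vehicle, and KL null mice injected with vehicle. FGF23 was given at 500 ng per g body weight and saline as 100 µl, both into the peritoneum, and the mice were killed 1 hour later, after 5 to 8 weeks on standard diet. The strain label differs between the genotypes: it is C57BL/6 for wild type and a mixed background that includes C57BL/6 for KL null, although the protocol calls the wild-type mice littermates. Genotype and strain label go together in these arrays, so no comparison can separate them. The labels number 4 replicates per group without saying whether each came from its own mouse, so the p-values measure the spread between these 12 samples. Other treatment arms named in the protocol were not analysed here.

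The deposited values are log2 expression values per probe set, made by the authors with RMA in Partek 6.2, per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a probe set on a log scale, so a difference of 1 on this scale is a doubling of signal. RMA compresses the folds of dim probe sets, and log2 values on an array are no absolute amounts, so levels of different probe sets were not set against each other. The values of the 12 arrays did not have a common distribution, since their standard deviations differed. Background correction and probe-level settings were not given in the sources used here. Scanner files were not used here, so no probe set could be tested against its background. The number of arrays, 4 per group, limits the precision.

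The value table held 28853 probe sets. Through the platform annotation supplied with it, 21789 of them had 1 gene symbol, 1621 had several and 5443 had none, and no gene was named from the last 2 kinds. The Entrez identifiers of 21698 of the probe sets with 1 symbol matched the mouse RefSeq gene table of GRCm38.p6, and 0 symbols needed an update. This gave 19938 genes, 999 of them with more than 1 probe set, and each gene was represented by its probe set with the highest mean over the 12 arrays. In KL null against wild type, 90 called genes had several probe sets and 8 of them had another probe set with the opposite sign of change, of which 0 passed the test in that direction. No coordinates are given, because the annotation of the array and the gene table need not share a build.

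Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, moderated). A single fit with 3 group means and 9 residual degrees of freedom was made over all 12 arrays, so that the groups share 1 estimate of the spread per gene. A gene was called when its Benjamini-Hochberg adjusted p over all 19938 genes was below 0.05, and every adjusted p of a gene comes from that test unless another is named. Folds are 2 to the power of the log2 difference, and errors of single groups are standard deviations over 4 arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

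The design, the rule for the genes named, the alternatives and 25 gene lists were fixed before the data were examined. The lists cover phosphate and vitamin D handling, immediate early genes, FGF and MAPK feedback genes, EGF receptor ligands and receptors, distal calcium and magnesium transport, distal sodium and potassium transport, the renin-angiotensin system, fibrosis, tubule injury, immune cells, interferon-stimulated genes, proximal tubule, thick ascending limb and distal convoluted tubule, collecting duct, podocytes, endothelium, adrenal gland, adipocytes, blood, fatty acid oxidation, NRF2, the circadian clock, glucocorticoid response, the cell cycle and WNT targets. Of their 517 entries 470 were measured, and some genes stand in more than 1 list. Each list was compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the 25 lists. The same test with an estimated correlation and the self-contained test fry were alternatives. The count of members passing after adjustment over the list alone was made with the same limma p-values.

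The named genes are, for each comparison against vehicle, the 7 largest increases and the 7 largest decreases among called genes whose groups do not overlap, without predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs, olfactory receptors, immunoglobulin segments and unnamed loci. Where no gene passed in a direction, the 3 with the smallest p stand in. Kl, Cyp27b1, Slc34a1, Slc34a3, Egr1, Fos, Dusp6, Hbegf, Trpv5 and Slc12a3 were named in advance, together with the 3 members of smallest p of each called list. Cyp24a1, also named in advance, was not analysed here. For the direct contrast of FGF23 with KL null, and for genes called in both comparisons, 5 genes per class with the smallest sum of the p-values were taken. Any other gene named here was chosen after its values were seen.

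Both comparisons use the same 4 vehicle arrays. Chance overlap was therefore simulated with 20 sets of unchanged groups that share their controls. In these sets all arrays, vehicle included, were drawn anew, with genes independent of each other. The vehicle arrays were also split 2 against 2 in all 6 ways. The labels number the replicates 1 to 4 in every group without saying what a number means. Deviations from the group means of same-numbered FGF23 and KL null arrays correlated at 0.143 to 0.259 across genes, above 0.1 in all 4 pairs, and 3 of the 4 arrays correlated best with the array of their own number. By the rule fixed before the comparison of fits, those 2 groups were read as paired, as a hint from the data and not from the labels. The pairs with vehicle arrays did not meet that rule. Replicates 1 and 2 of both the FGF23 and the KL null group also had the lowest spread of all arrays. The correlations therefore cannot tell a pairing from that shared spread. The main fit takes no account of such pairs, and a block fit of the 2 groups stands beside it.

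The alternatives were a further quantile normalization, centring of each array on its median, removal of genes with a mean log2 value under 5 or below the median gene, the mean of all probe sets of a gene, every probe set or every table entry tested, only the 2 groups compared, trend and robust moderation, array quality weights, an unmoderated model, the replicate number as a block, a fold of at least 1.5, and each of the 12 arrays left out in turn. Chosen after seeing the data were fits without the arrays of lowest spread, a fit with the standard deviation of each array as a covariate, and a block fit of only FGF23 and KL null arrays. The mean absolute log2 difference between any 2 arrays was at least 0.141, so no array is a copy of another.

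The procedure was tested on simulated data in which 67 genes were changed 1.5-fold, 67 changed 2-fold and 66 changed 3-fold. In the simulated FGF23 against vehicle comparison over 19938 genes, limma recovered 67.2% of the genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 3-fold, with 7 false calls. In the simulated KL null comparison over 19938 genes these shares were 71.6%, 98.5% and 100%, with 6 false calls. A list shifted by 0.3 on the log2 scale was called in each comparison, with 0 other lists called. The simulated genes varied independently of each other, so this does not show how often lists are called falsely in the real arrays. There the estimated correlation within a list reached 0.529, and other splits of the FGF23 and vehicle arrays called up to 14 lists.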

Results

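Gene expression was measured in kidney of female mice on 12 whole-transcript arrays, 4 per group. The groups were wild-type mice killed 1 hour after an injection of 500 ng per g recombinant FGF23, wild-type mice given saline vehicle, and KL null mice given vehicle. FGF23 is a bone-derived hormone that lowers phosphate reabsorption and 1,25-dihydroxyvitamin D synthesis in the kidney, and klotho, the product of Kl, is the co-receptor it needs for signalling through FGF receptors. The series was set up to look for FGF23-responsive pathways in renal phosphate and vitamin D handling. Values are log2 RMA signals, given as mean ± SD over 4 arrays, and adjusted p-values of genes come from limma over 19938 genes. The number of arrays limits the precision of every comparison.

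The first principal component held 33.6% of the variance and parted the KL null arrays from both wild-type groups. The second component, with 23.5%, followed the standard deviation of the log2 values on each array, with Pearson's r = -0.944 (permutation p = 2e-05) and Spearman's rho = -0.881 (permutation p = 0.00044) over the 12 arrays. The 2 FGF23 arrays farthest from the median spread, WT FGF23 replicates 1 and 2, had standard deviations of 2.166 and 2.167. Without them r was -0.875. KL null replicates 1 and 2 had the next lowest values, 2.195 and 2.217, and the other 8 arrays lay between 2.23 and 2.281.

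**Figure D1:**
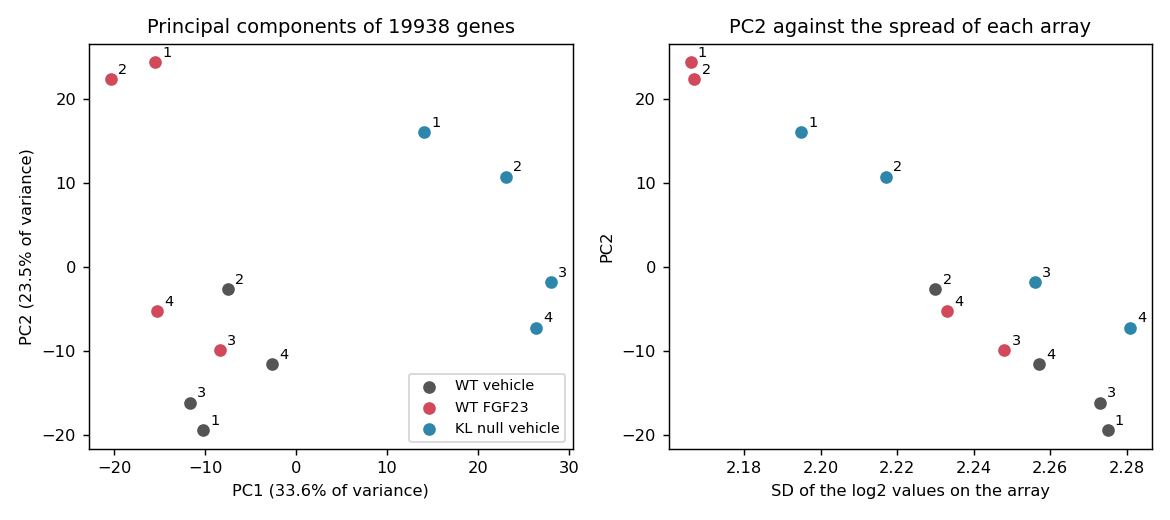
Left, scores of the 12 arrays on the first and second principal components of 19938 genes, coloured by group and numbered by replicate; right, the second component against the standard deviation of the log2 values on each array. KL null arrays stand to the right on the first component, and the arrays of lowest spread, WT FGF23 replicates 1 and 2 at 2.166 and 2.167, stand highest on the second.

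FGF23 against vehicle in wild-type mice asks which kidney transcripts respond within 1 hour of the hormone. Egr1, a transcription factor induced within minutes of ERK activation, rose from 6.16 ± 0.17 to 9.34 ± 0.35 (SD, n = 4), a 9.05-fold increase (log2 fold 3.18, SE 0.144, adjusted p = 1.55e-08). Hbegf, which encodes the EGF receptor ligand HB-EGF, rose 3.10-fold from 7.31 ± 0.17 to 8.94 ± 0.50 (adjusted p = 0.00153). Dusp6, a phosphatase that dephosphorylates ERK and is itself induced by FGF signalling, rose 2.42-fold from 8.83 ± 0.11 to 10.11 ± 0.12 (adjusted p = 1.6e-06). Each of these 3 genes was higher in all 4 FGF23 arrays than in any vehicle array. Kl itself did not pass the test after FGF23, at 10.61 ± 0.13 with vehicle and 10.51 ± 0.08 with FGF23 (adjusted p = 0.551).

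In all, 17 genes were called, 16 higher and 1 lower, 4 of them at least 2-fold higher. At an unadjusted p below 0.05 there were 3063 genes, against 997 by chance, and in 1397 genes (7.01%) the 4 FGF23 and 4 vehicle arrays did not overlap, against 2.86% by chance. The log2 folds correlated with the mean value of the gene at -0.392. That correlation was -0.0614 after a further quantile normalization and -0.0125 with array spread as a covariate. The excess over chance can therefore not be read as a number of genes that respond to FGF23. Zfp36, an RNA-binding protein that destabilises AU-rich mRNAs, rose by 1.15 on the log2 scale (adjusted p = 0.0127) and the immediate early gene Ier2 by 0.97 (adjusted p = 0.00105). Dusp4, another MAPK phosphatase, rose by 0.91, the clock-linked repressor Bhlhe40 by 0.85 and the receptor tyrosine kinase inhibitor Spry4 by 0.49, each with an adjusted p of 0.047. The other called genes, listed here after their values were seen, were Junb, Nab2, Sertad1, Chka, Ddit3, Dnajc17, Prr5l and Rbm3os among those that rose, and Gm11992, a predicted gene, which fell. Among the genes covered by the naming rule no decrease passed: the 3 smallest p-values belonged to Slco1a4 (log2 fold -0.52, adjusted p = 0.0842), Acot3 (-0.53, 0.0846) and Tmem140 (-0.69, 0.114). Of these, Acot3 passed in 3 of 25 alternatives, among them without WT vehicle replicate 1 (adjusted p = 0.0475, 0.0389 to 0.612 over the alternatives). Tmem140 passed in 1, with a trended and robust moderation (0.0497, and up to 0.996), and Slco1a4 in 0 (0.053 to 0.883).

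**Figure D2:**
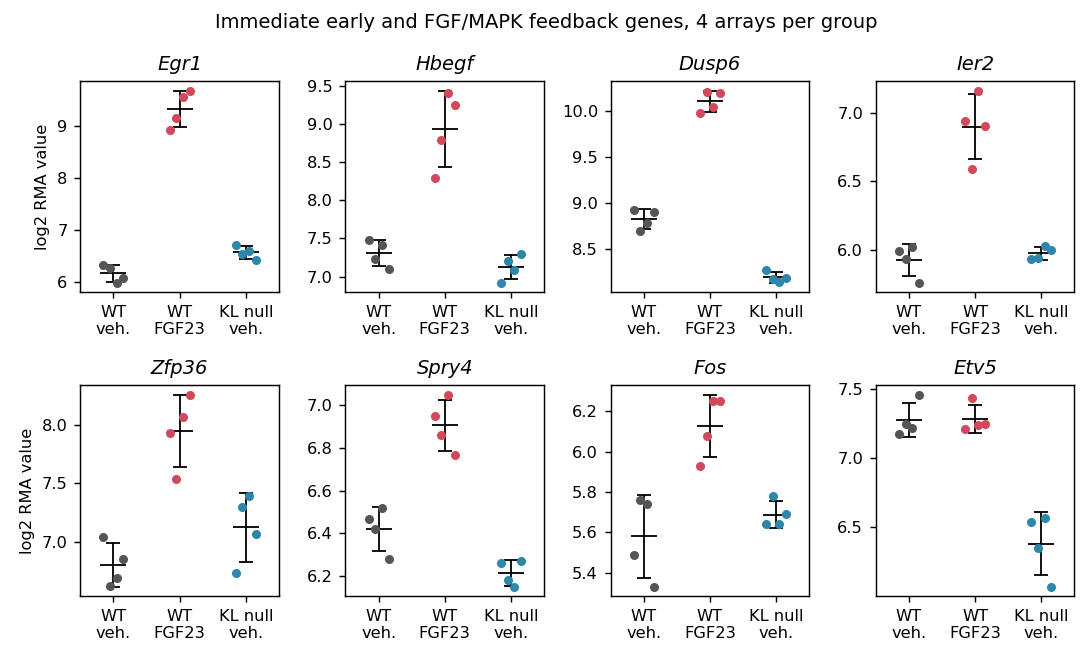
Log2 RMA values of 8 genes on each array (points), with the mean and SD of the 4 arrays per group (bars). The genes are immediate early and FGF/MAPK feedback genes, and Hbegf of the EGF receptor list. Egr1, Hbegf, Dusp6, Ier2, Zfp36 and Spry4 passed the test after FGF23, while Fos (adjusted p = 0.0998) and Etv5 did not, and Dusp6 and Etv5 were lower in KL null than in wild-type vehicle kidneys.

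Of 32 immediate early genes 4 rose (Egr1, Ier2, Zfp36 and Junb) and 0 fell, 10 rose when adjusted over the list alone, and 29 had a positive fold. The list stood above the other genes (median log2 fold 0.26, camera adjusted p = 5.34e-09), but not with an estimated correlation (adjusted p = 0.11 with an estimated correlation). Fos, a member of the list, was at 5.58 ± 0.21 and 6.13 ± 0.15, which did not pass over all genes (adjusted p = 0.0998) except with array quality weights (0.0341, and up to 0.305 over the alternatives). Of 24 FGF and MAPK feedback genes 3 rose (Dusp6, Dusp4 and Spry4), 8 when adjusted over the list alone, with a median log2 fold of 0.17 (camera adjusted p = 1.2e-05). This was the only one of the 25 lists called with an estimated correlation (adjusted p = 0.026 with an estimated correlation), and its adjusted p lay between 3.17e-09 and 0.026 over 26 alternatives. In the list of EGF receptor ligands, receptors and sheddases, 1 of 16 genes rose, Hbegf, also when adjusted over the list alone, and the list was not called (adjusted p = 0.394).

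Circadian clock genes were also higher as a list (median 0.27, camera adjusted p = 0.000548, adjusted p = 0.233 with an estimated correlation). Of its 18 members 1 rose over all genes, Bhlhe40, and 7 rose and 1 fell when adjusted over the list alone. Ciart (log2 fold 1.27, 5.96 ± 0.34 to 7.23 ± 0.74) and Dbp (log2 fold 0.57) each had an adjusted p of 0.241. Glucocorticoid-responsive and stress genes (median 0.23), WNT targets (median 0.13) and adrenal gland markers (median 0.18) each had a camera adjusted p of 0.028. In these 3 lists 0 members passed over all genes or adjusted over the list alone, and the adjusted p with an estimated correlation was 0.664, 0.177 and 0.388. They were also set against 10000 random lists of the same size matched on mean value. Of these, 14.6% had a median as high as the adrenal list, 9.23% as high as the WNT list and 0% as high as the glucocorticoid list. The adrenal and WNT medians are thus not unusual for genes of their mean value. The members with the smallest p were Errfi1 (log2 fold 0.50, adjusted p = 0.241), Dusp1 (0.81, 0.253) and Per1 (0.83, 0.265) among glucocorticoid-responsive genes, and Nkd1 (0.27, 0.245), Myc (0.31, 0.252) and Bambi (0.26, 0.253) among WNT targets. Errfi1 also stands in the FGF and MAPK feedback list, Dusp1 and Myc in the immediate early list and Per1 in the clock list. These lists are therefore not separate evidence. Of the adrenal markers, Cyp11b1 of the adrenal cortex was at 4.45 ± 0.21 and 4.96 ± 0.29 (adjusted p = 0.245), with Chga (log2 fold 0.33, adjusted p = 0.276) and Cyp21a1 (0.30, 0.282) next.

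Lists of tubule and podocyte genes, of fatty acid oxidation and of interferon-stimulated genes lay slightly lower after FGF23. In these 8 lists called lower, 0 members passed over all genes. The proximal tubule list had a median log2 fold of -0.14 and 21 of 24 members with a negative fold (camera adjusted p = 0.000141, adjusted p = 0.177 with an estimated correlation). Its members with the smallest p were Fbp1 of gluconeogenesis (log2 fold -0.16, adjusted p = 0.316), Acsm2 (-0.16, 0.371) and the myo-inositol oxygenase Miox (-0.18, 0.387). Median folds, camera adjusted p and adjusted p with an estimated correlation were -0.11, 0.00127 and 0.292 for fatty acid oxidation and PPAR-alpha targets, and -0.07, 0.00321 and 0.177 for collecting duct markers. They were -0.11, 0.00742 and 0.264 for distal calcium and magnesium transport, and -0.09, 0.00742 and 0.33 for distal sodium and potassium transport. Interferon-stimulated genes had -0.10, 0.0146 and 0.388, thick ascending limb and distal convoluted tubule markers -0.07, 0.0146 and 0.338, and podocyte markers -0.11, 0.028 and 0.341. Smallest in p were Acot3, Cyp4a10 (-0.28, 0.276) and Hadhb (-0.18, 0.332) for fatty acid oxidation, and Slc26a4 (-0.26, 0.26), Atp6v0d2 (-0.27, 0.283) and the sodium channel subunit Scnn1g (-0.22, 0.307) for the collecting duct. For the distal lists they were calbindin, Calb1 (-0.44, 0.241), the claudin Cldn10 (-0.26, 0.276), the regulatory kinase Wnk4 (0.27, 0.253), Scnn1b (-0.23, 0.342) and Tmem52b (-0.28, 0.241). For interferon-stimulated genes they were Rtp4 (-0.30, 0.298), Mx2 (-0.29, 0.312) and Ifit3 (-0.30, 0.357), and for podocytes Tcf21 (-0.41, 0.327), Podxl (-0.15, 0.459) and Cdkn1c (-0.16, 0.476). Adjusted over the list alone, 1 fatty acid oxidation gene fell, as did 2 genes of the thick ascending limb and distal convoluted tubule list, and 0 genes passed in the other 6. Of these 8 lists, 2 were still called lower without WT FGF23 replicates 1 and 2, the arrays of lowest spread (proximal tubule and fatty acid oxidation), and 1 after a further quantile normalization (interferon-stimulated genes).

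The phosphate and vitamin D genes did not pass the test at 1 hour. Cyp27b1, the 1-alpha-hydroxylase that makes 1,25-dihydroxyvitamin D, was at 6.75 ± 0.37 with vehicle and 6.28 ± 0.39 with FGF23 (log2 fold -0.47, SE 0.243, adjusted p = 0.362). The sodium-phosphate cotransporters of the proximal tubule were at 12.93 ± 0.08 and 12.88 ± 0.02 for Slc34a1 (adjusted p = 0.707) and at 9.59 ± 0.10 and 9.43 ± 0.30 for Slc34a3 (adjusted p = 0.593). The epithelial calcium channel gene Trpv5 had a log2 fold of -0.20 (adjusted p = 0.298) and the sodium-chloride cotransporter gene Slc12a3 of -0.14 (adjusted p = 0.449). Of the 19 genes of the phosphate and vitamin D list 0 passed over all genes and 1 was higher when adjusted over the list alone (camera adjusted p = 0.22). The remaining lists were not called either. Endothelial, erythroid, adipocyte and fibrosis genes each had an adjusted p of 0.963, immune cells 0.418, NRF2 genes 0.0913, the renin-angiotensin system 0.105, tubule injury markers 0.498 and cell cycle genes 0.136. Adjusted over the list alone, 1 renin-angiotensin gene was lower, 1 injury marker was higher, and 0 genes passed in the other 7 of these lists. For the EGF receptor, adipocyte, endothelial, fibrosis and injury lists the median, the mean and the test differed in sign.

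The number of calls was small and moved by more than 1.5 times with every array left out except KL null replicate 4 (14 calls). It was 8, 5, 4 and 8 without WT FGF23 replicates 1 to 4, 7, 4, 4 and 11 without WT vehicle replicates 1 to 4, and 9, 10 and 5 without KL null replicates 1 to 3. Egr1, Dusp6, Hbegf and Ier2 passed in all 12 of these fits. Hbegf and Ier2 lost their calls in the unmoderated model (adjusted p = 0.137 and 0.0596, from 7.68e-06 and 0.00011 over the alternatives). Zfp36 lost its call without WT FGF23 replicate 3 and WT vehicle replicates 2 and 3 (highest adjusted p = 0.0806, without WT vehicle replicate 2), Dusp4 in 9 fits (0.235), Bhlhe40 in 11 (0.175) and Spry4 in all 12 (0.175), these 3 most without WT FGF23 replicate 2. Over all alternatives their adjusted p ran from 0.00164 to 0.162, 0.0114 to 0.479, 0.00456 to 0.23 and 0.0373 to 0.448, in that order, against 2.74e-10 to 0.000177 for Egr1 and 2.19e-08 to 0.000368 for Dusp6.

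The number of called lists was 9 without WT FGF23 replicate 1 and 9 without WT vehicle replicate 3. Calls were lost without WT FGF23 replicate 1 for the glucocorticoid (adjusted p = 0.124), podocyte (0.109), distal sodium and potassium (0.0958), adrenal, interferon and thick ascending limb lists (each 0.0821). Without WT vehicle replicate 3 they were lost for the glucocorticoid (0.146), podocyte (0.101), adrenal (0.0588), WNT and thick ascending limb lists (both 0.0525). They were also lost without WT FGF23 replicate 2 for the glucocorticoid and thick ascending limb (both 0.0688) and interferon lists (0.0552), without WT FGF23 replicates 3 and 4 for WNT targets (0.0585 and 0.135), and without WT vehicle replicate 4 for WNT targets (0.0579) and adrenal markers (0.0502). Calls were gained by NRF2 genes without WT FGF23 replicate 1 (0.0268), renin-angiotensin genes without WT FGF23 replicate 4 (0.0274), fibrosis genes without WT vehicle replicate 4 (0.029), and phosphate and vitamin D and cell cycle genes without WT vehicle replicate 2 (both 0.0459).

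KL null against wild type, both with vehicle, asks how the kidney differs without klotho. Kl fell from 10.61 ± 0.13 in wild type to 9.72 ± 0.07 in KL null (log2 fold -0.89, SE 0.0831, adjusted p = 1.75e-05), with the 4 KL null arrays all below the 8 wild-type arrays. Which exons its probe set covers is not known here, so it may lie partly outside the deleted part, and the remaining signal does not measure intact Kl mRNA. Cyp27b1 was 7.37-fold higher in KL null, at 6.75 ± 0.37 and 9.64 ± 0.51 (log2 fold 2.88, SE 0.243, adjusted p = 7.82e-06). Among FGF and MAPK feedback genes, Etv1, an ETS factor induced by FGF receptors, fell by 1.95 on the log2 scale (adjusted p = 5.52e-07), Etv5 by 0.90 (adjusted p = 0.000198) and Dusp6 by 0.64 (adjusted p = 0.000389). Of the 24 genes of that list 5 fell, 1 rose and 18 did not pass, with 5 and 1 also when adjusted over the list alone (median -0.06, camera adjusted p = 0.00841, adjusted p = 0.216 with an estimated correlation).

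**Figure D3:**
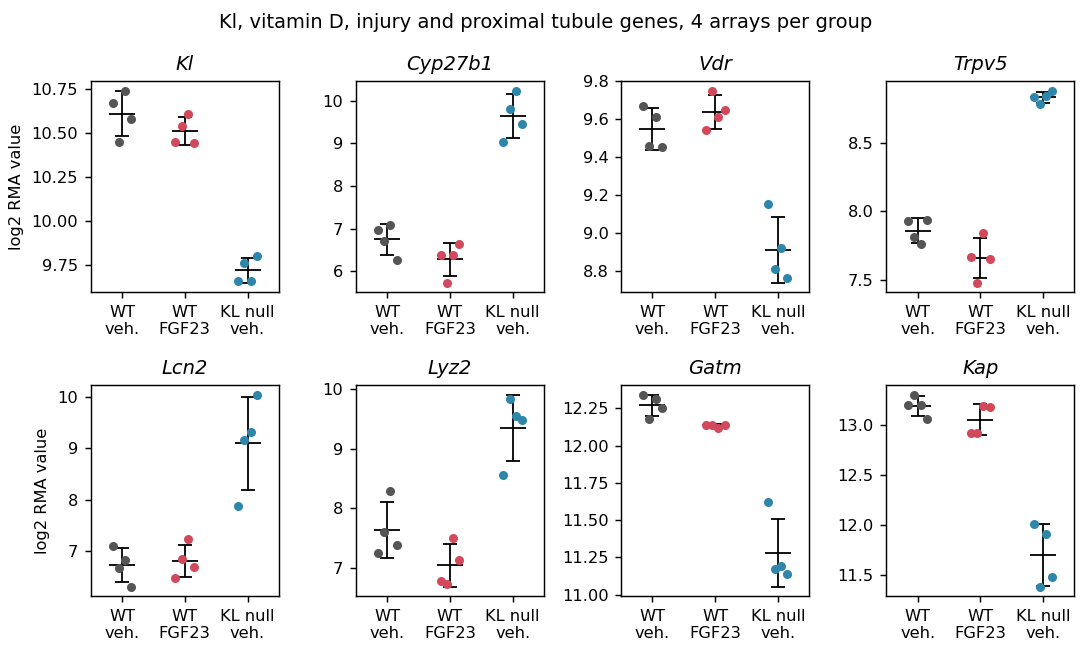
Log2 RMA values of Kl, genes of vitamin D and calcium handling (Cyp27b1, Vdr, Trpv5), the injury marker Lcn2, the macrophage gene Lyz2 and the proximal tubule genes Gatm and Kap on each array (points), with the mean and SD of the 4 arrays per group (bars). Kl, Vdr, Gatm and Kap were lower and the other 4 higher in KL null than in wild-type vehicle kidneys.

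In all, 1598 genes were called, 713 higher and 885 lower in KL null, of which 58 were at least 2-fold higher and 78 at least 2-fold lower. With each array centred on its median the count was 1667, split 428 higher and 1239 lower. At an unadjusted p below 0.05 there were 4241 genes, against 997 by chance, and in 2750 genes (13.8%) the groups did not overlap, against 2.86% by chance. The largest increases named by the rule were in the amino acid transporter gene Slc7a13 (11.5-fold, 5.79 ± 0.19 to 9.31 ± 1.40, adjusted p = 0.000506), the macrophage elastase Mmp12 (8.85-fold, adjusted p = 8.75e-05) and the uridine phosphorylase Upp2 (7.74-fold, adjusted p = 5.36e-05). They were followed by Cyp27b1, given above (7.37-fold), Gpnmb of activated macrophages (7.12-fold, adjusted p = 0.00107), Lcn2 (5.23-fold, adjusted p = 0.000486) and the fatty acid hydroxylase Cyp4a12b (3.51-fold, adjusted p = 6.9e-05). The spread within KL null was wide for several of them, with an SD of 1.07 for Mmp12 and 1.35 for Gpnmb.

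Of the 7 largest decreases named by the rule, 2 were in steroid-metabolising genes and 3 in genes of the Slc22 family of organic anion transporters. Akr1c18, a 20-alpha-hydroxysteroid dehydrogenase, was at 12.24 ± 0.34 in wild type and 7.55 ± 0.70 in KL null, 25.8-fold lower (adjusted p = 2.78e-06), and its family member Akr1c14 was 8.10-fold lower (adjusted p = 8.61e-05). The organic anion transporter gene Slc22a7 was 24.3-fold lower (adjusted p = 2.78e-06), Slc22a19 10.3-fold lower (adjusted p = 7.41e-06) and Slc22a26 10.2-fold lower (adjusted p = 0.00651). Wild-type vehicle replicate 4 stood far below the other vehicle arrays for Slc22a26, at 6.09 against 8.55 to 8.98. WT FGF23 replicates 1 and 2 were as low, at 5.79 and 5.97, against 8.61 and 8.7 in replicates 3 and 4. The level thus varied widely among wild-type arrays, which limits the fold. The gene lost its call in the unmoderated model (adjusted p = 0.0533, and 0.00083 to 0.0533 over the alternatives). Ly6f was 8.35-fold lower (adjusted p = 5.88e-06) and the ubiquitin ligase gene Rnf24 7.16-fold lower (adjusted p = 2.03e-06).

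Proximal tubule markers were the list with the smallest p. Of 24 members 13 fell and 2 rose, or 17 and 2 when adjusted over the list alone, with a median log2 fold of -0.35 (camera adjusted p = 3.52e-08, adjusted p = 0.173 with an estimated correlation). Kap, an androgen-regulated protein, fell 2.82-fold (adjusted p = 1.05e-05), Gatm of creatine synthesis by 0.99 on the log2 scale (adjusted p = 3.55e-05), and the endocytic receptor Lrp2 by 0.50 (adjusted p = 0.00175). The 2 members that rose were Slc7a13, given above, and the cytochrome Cyp2e1 (log2 fold 1.33, adjusted p = 0.000388). In the phosphate and vitamin D list 7 of 19 genes fell and 1 rose, or 10 and 2 when adjusted over the list alone (median -0.27, camera adjusted p = 0.0014, adjusted p = 0.252 with an estimated correlation). The vitamin D receptor gene Vdr fell by 0.64 (adjusted p = 0.000921) and Slc34a1 by 0.27, from 12.93 ± 0.08 to 12.67 ± 0.03 (adjusted p = 0.0305), whereas Slc34a3 at 9.59 ± 0.10 and 9.22 ± 0.26 did not pass (adjusted p = 0.144) but did in 4 alternatives, among them without KL null replicate 1 (0.0444, and 0.00876 to 0.36 over the alternatives). Cyp27b1 was the member that rose. Slc34a1 lost its call without WT vehicle replicates 1 and 3 and KL null replicates 2 to 4 (highest adjusted p = 0.102, without WT vehicle replicate 3, and 0.00338 to 0.102 over the alternatives).

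Distal calcium genes moved both ways, and the distal calcium and magnesium list was not called (camera adjusted p = 0.441). Of 17 members 5 rose and 3 fell, or 5 and 4 when adjusted over the list alone. Trpv5 rose 1.96-fold from 7.86 ± 0.09 to 8.83 ± 0.04 (adjusted p = 1.05e-05), and the calcium-binding S100g and the channel Trpv6, named after their values were seen, rose by 0.74 and 0.53 on the log2 scale (adjusted p = 0.000689 and 0.00537). In the distal sodium and potassium list 1 of 21 genes fell, Slc12a3, by 0.32 (adjusted p = 0.0469), and 0 when adjusted over the list alone (median -0.11, camera adjusted p = 0.0166, adjusted p = 0.413 with an estimated correlation). The kinase gene Oxsr1 (log2 fold -0.26, adjusted p = 0.0579, and 0.0224 to 0.178 over the alternatives) and the channel Kcnj16 (-0.19, 0.188) came next. Slc12a3 lost its call without WT FGF23 replicate 3, WT vehicle replicates 1, 3 and 4 and KL null replicates 2 to 4 (highest adjusted p = 0.151, without WT vehicle replicate 3, and 0.00914 to 0.151 over the alternatives), and the list lost its call without KL null replicate 1 (0.0933). Of the 11 renin-angiotensin genes 2 fell, Ace by 1.35 (adjusted p = 0.00047) and the aminopeptidase Anpep by 0.61 (adjusted p = 0.00497), or 2 with 1 higher when adjusted over the list alone (median -0.08, camera adjusted p = 0.0358, adjusted p = 0.223 with an estimated correlation). Angiotensinogen, Agt, did not pass (log2 fold 0.42, adjusted p = 0.0962) but did in 2 alternatives, among them without KL null replicate 1 (0.0486, and 0.0318 to 0.229 over the alternatives). The list lost its call without KL null replicates 1 and 4 (adjusted p = 0.0658 and 0.0538).

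Of 19 tubule injury markers 7 rose and 0 fell, 12 when adjusted over the list alone (median 0.40, camera adjusted p = 4.02e-06, adjusted p = 0.223 with an estimated correlation). Lcn2, a siderophore-binding protein of injured tubules, went from 6.71 ± 0.33 to 9.10 ± 0.91, Vcam1 rose by 0.83 on the log2 scale (adjusted p = 0.000486) and the keratin gene Krt8 by 0.46 (adjusted p = 0.00461). Of 24 immune cell and chemokine genes 5 rose and 1 fell, or 8 and 1 when adjusted over the list alone (median 0.24, camera adjusted p = 0.0014, adjusted p = 0.252 with an estimated correlation). The myeloid genes Lyz2 (log2 fold 1.71, adjusted p = 0.0011), Itgax (1.02, 0.0103) and Itgam (0.88, 0.00159) rose. Itgax lost its call in the unmoderated model (adjusted p = 0.06, and 0.00133 to 0.06 over the alternatives). Of 18 interferon-stimulated genes 3 fell and 1 rose, or 4 and 1 when adjusted over the list alone (median -0.21, camera adjusted p = 0.000368, adjusted p = 0.252 with an estimated correlation). Among them the guanylate-binding Gbp3 fell by 2.42 (adjusted p = 0.0013), the transcription factor Irf7 by 0.48 (adjusted p = 0.0123) and the antiviral Rsad2 by 0.58 (adjusted p = 0.0293). Irf7 lost its call without WT vehicle replicates 1 and 3 and KL null replicate 3 (highest adjusted p = 0.0507, without WT vehicle replicate 3, and 0.000982 to 0.0507 over the alternatives). Rsad2 lost it without WT vehicle replicates 2 to 4 and KL null replicates 2 to 4 (highest 0.0926, without KL null replicate 3, and 0.00128 to 0.0933 over the alternatives).

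Circadian clock genes were higher as a list, with 8 of 18 members up and 2 down, or 9 and 3 when adjusted over the list alone (median 0.41, camera adjusted p = 0.00383, adjusted p = 0.252 with an estimated correlation). Cry2 rose by 0.94 on the log2 scale (adjusted p = 0.00125), Per3 by 0.93 (adjusted p = 0.00134) and Bhlhe41 1.99-fold (adjusted p = 0.00289). Arntl, which acts in antiphase to these repressors and was named after its values were seen, fell by 1.06 (adjusted p = 0.00646). Of 19 glucocorticoid-responsive and stress genes 2 rose, Lcn2 and Nfkbia, as when adjusted over the list alone (median 0.50, camera adjusted p = 0.0107, adjusted p = 0.597 with an estimated correlation). Nfkbia (log2 fold 0.69, adjusted p = 0.0219) lost its call without WT vehicle replicates 1 and 3 and KL null replicates 2 to 4 (highest adjusted p = 0.078, without KL null replicate 3, and 0.000256 to 0.0834 over the alternatives). The metallothionein Mt2 (log2 fold 0.80, adjusted p = 0.133) passed only without KL null replicate 1 among these fits (0.0464, and 0.00464 to 0.322 over the alternatives). The list lost its call without KL null replicate 4 (adjusted p = 0.111).

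Of 11 podocyte markers 2 fell and 6 when adjusted over the list alone (median -0.26, camera adjusted p = 0.000823, adjusted p = 0.246 with an estimated correlation), among them Npnt, which fell by 0.60 (adjusted p = 0.0173), and Podxl, by 0.37 (adjusted p = 0.027). Clic5 of the foot processes had a log2 fold of -0.27 (adjusted p = 0.0527, and 0.0158 to 0.146 over the alternatives), and passed in 10 of them, among these without WT FGF23 replicate 1 (0.0456) and WT vehicle replicate 4 (0.0411). Npnt lost its call without WT vehicle replicates 1 and 3, and Podxl without those and KL null replicates 1 to 3 (highest adjusted p = 0.0682 and 0.091, both without WT vehicle replicate 3, and from 0.00352 and 0.00927 over the alternatives).

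Collecting duct markers had 1 of 20 lower, the ammonia transporter gene Rhbg (log2 fold -0.35, adjusted p = 0.0298), also when adjusted over the list alone (median -0.12, camera adjusted p = 0.0166, adjusted p = 0.252 with an estimated correlation). The anion exchangers Slc26a4 (-0.22, 0.17) and Slc4a1 (-0.23, 0.203, and 0.0306 to 0.435 over the alternatives) came next. Rhbg lost its call without WT vehicle replicates 1, 3 and 4 and KL null replicates 2 to 4 (highest adjusted p = 0.102, without KL null replicate 3, and 0.00312 to 0.102 over the alternatives). Of 20 endothelial markers 0 passed, over all genes or adjusted over the list alone (median -0.10, camera adjusted p = 0.0124, adjusted p = 0.522 with an estimated correlation). VE-cadherin, Cdh5 (-0.33, 0.073), passed without WT FGF23 replicate 1 (0.0397, and 0.0379 to 0.228 over the alternatives), endoglin, Eng (-0.35, 0.132), without WT vehicle replicate 4 (0.0158, and 0.0158 to 0.36), and Emcn did not (-0.28, 0.116). Without KL null replicate 1 the collecting duct and endothelial lists lost their calls (adjusted p = 0.0629 and 0.17). Thick ascending limb and distal convoluted tubule markers were not called (adjusted p = 0.8), with 3 of 18 higher and 1 lower.

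The other lists were not called in KL null. Immediate early genes had an adjusted p of 0.0831, with Egr1 at 6.16 ± 0.17 and 6.56 ± 0.12 (adjusted p = 0.106, and 0.023 to 0.277 over the alternatives) and Fos at 5.58 ± 0.21 and 5.69 ± 0.07 (adjusted p = 0.64). Hbegf did not pass either (log2 fold -0.18, adjusted p = 0.67), and the EGF receptor list had an adjusted p of 0.736. Fatty acid oxidation genes had 3 members up and 3 down of 23 (adjusted p = 0.322), NRF2 genes 2 and 2 of 20 (0.378) and WNT targets 3 and 0 of 17 (0.374). Fibrosis genes had 4 members up and 0 down of 25 (adjusted p = 0.734), among them Timp1, named after its values were seen, with a log2 fold of 1.24 (adjusted p = 2.78e-06). Adrenal markers had an adjusted p of 0.274, cell cycle genes 0.271, erythroid markers 0.553 and adipocyte markers 0.798. Adjusted over the list alone, the counts higher and lower were 3 and 1 for immediate early genes, 2 and 3 for the EGF receptor list, 4 and 3 for fatty acid oxidation, 2 and 2 for NRF2 and 3 and 0 for WNT. They were 4 and 0 for fibrosis, 2 and 0 for adrenal, 1 and 0 for cell cycle, 3 and 2 for thick ascending limb and distal convoluted tubule markers, and 0 for erythroid and adipocyte markers. For the EGF receptor, adipocyte and fibrosis lists the median, the mean and the test differed in sign. The immediate early list was called higher without WT vehicle replicate 1 and without KL null replicate 1 (adjusted p = 0.0165 and 0.00596), and the fatty acid oxidation list without WT vehicle replicate 4 (0.0491).

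**Figure D4:**
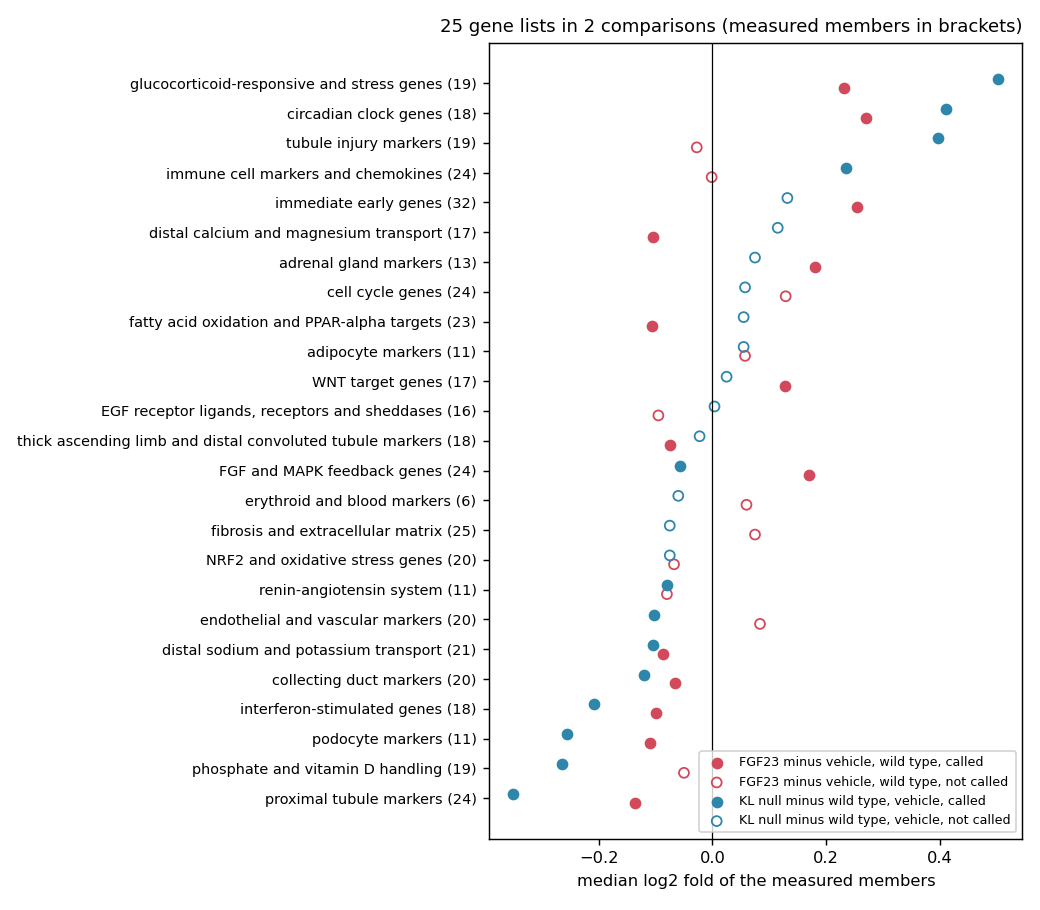
Median log2 fold of the measured members of each of the 25 gene lists (number of members in brackets) for FGF23 minus vehicle in wild type and for KL null minus wild type with vehicle, filled where camera with a preset correlation called the list and open where it did not. Proximal tubule markers had the lowest median in KL null, -0.35. The FGF and MAPK feedback list was called in both comparisons in opposite directions, at 0.17 and -0.06. The other lists called in both went the same way in each. Circadian clock and glucocorticoid-responsive genes were higher, and proximal tubule, podocyte, collecting duct, distal sodium and potassium and interferon-stimulated genes were lower. Both comparisons use the same vehicle arrays.

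Of the 13 lists called in this comparison, 0 were called with an estimated correlation. The count of 1598 genes depended on single arrays: it was 831 and 828 without WT vehicle replicates 1 and 3, and 1003 and 856 without KL null replicates 2 and 3.

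FGF23 in wild type against KL null tests whether the effects of FGF23 and of genotype, each measured against the same vehicle arrays, differ. Dusp6 had the smallest p, 3.76-fold higher with FGF23 than in KL null (10.11 ± 0.12 against 8.20 ± 0.06, adjusted p = 9.54e-09). The ubiquitin ligase gene Rnf186 (2.23-fold, adjusted p = 2.83e-05), the phosphatase regulator Ppp1r16b (2.46-fold, adjusted p = 3.46e-05), the thioesterase gene Lypla1 (1.24-fold, adjusted p = 0.0347) and Sectm1b (1.43-fold, adjusted p = 0.0345) were also higher with FGF23 than in KL null. Against vehicle, Lypla1 and Sectm1b did not rise with FGF23. Their FGF23 arrays, at 10.38 to 10.75 and 7.77 to 8.13, lay below the vehicle arrays, at 10.89 to 10.95 and 8.28 to 8.9. Lower with FGF23 than in KL null were the myeloid Fc receptor gene Fcgr3 (log2 fold -0.37, adjusted p = 0.0228), the tetraspanin Tspan4 (-0.39, 0.034), Tmem52b (-0.57, 0.000676), Flacc1 (-0.78, 0.000166) and Tprkb (-0.79, 0.000676). Fcgr3 and Tspan4 were not lower with FGF23 than with vehicle. They stood at 5.91 to 6.36 and 8.33 to 8.65 with FGF23, against 5.72 to 5.92 and 8.06 to 8.27 with vehicle. In all, 2386 genes differed, 1046 higher and 1340 lower with FGF23 than in KL null, with 5436 at an unadjusted p below 0.05 against 997 by chance, and 3211 (16.1%) without overlap against 2.86% by chance. Of the FGF and MAPK feedback list 11 of 24 genes were higher and 0 lower, or 13 and 1 when adjusted over the list alone (camera adjusted p = 2.94e-07, adjusted p = 0.00912 with an estimated correlation). Tubule injury markers had 8 of 19 genes lower with FGF23 than in KL null, or 12 when adjusted over the list alone (camera adjusted p = 4.72e-06, adjusted p = 0.366 with an estimated correlation). Immune cell genes had 6 of 24 lower (camera adjusted p = 0.00106) and immediate early genes 6 of 32 higher and 1 lower (0.00523), or 9 lower with 1 higher and 8 higher with 1 lower when adjusted over the list alone, and neither list held its call with an estimated correlation (adjusted p = 0.431 with an estimated correlation for both). Fatty acid oxidation genes had 1 of 23 higher and 6 lower (camera adjusted p = 0.00194), also when adjusted over the list alone, and proximal tubule markers 7 of 24 higher and 2 lower (0.0119), or 11 and 3 over the list alone (adjusted p = 0.431 with an estimated correlation for both). The distal calcium and magnesium list, with 2 of 17 higher and 8 lower (camera adjusted p = 0.0351, 3 and 8 over the list alone), had a median of 0.03 but a lower direction in the test. Of 19 phosphate and vitamin D genes 7 were higher and 1 lower (0.0386, 9 and 1 over the list alone). With an estimated correlation these 2 lists were not called (adjusted p = 0.431 and 0.721 with an estimated correlation). The circadian clock and glucocorticoid lists, called higher in both comparisons against vehicle, were not called in this contrast (camera adjusted p = 0.781 and 0.599). Nor were the collecting duct, distal sodium and potassium (both 0.938), podocyte (0.191) and interferon lists (0.219), called lower in both. Since both comparisons share the vehicle arrays, their agreement in direction is not independent.

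With only the 2 groups and the replicate number as a block, 2606 genes were called and Tspan4 no longer passed (adjusted p = 0.0755, and 0.00849 to 0.0993 over the alternatives). Lypla1 lost its call without WT FGF23 replicates 3 and 4 and KL null replicates 2 to 4 (highest adjusted p = 0.102, without WT FGF23 replicate 4), and Tspan4 without WT FGF23 replicates 2 to 4 and KL null replicates 2 to 4 (highest 0.0993, without WT FGF23 replicate 4). Sectm1b lost it without WT FGF23 replicates 1, 3 and 4 and KL null replicates 3 and 4 (highest 0.119, without KL null replicate 3), and Fcgr3 without WT FGF23 replicates 1, 2 and 4 and KL null replicates 3 and 4 (highest 0.0664, without WT FGF23 replicate 1). Over all alternatives the adjusted p ran from 0.00769 to 0.102 for Lypla1, 0.0119 to 0.119 for Sectm1b and 0.00775 to 0.206 for Fcgr3. The count was 1369 and 1574 without WT FGF23 replicates 2 and 4, 1218 without KL null replicate 3, and 944 without WT FGF23 replicates 1 and 2 together.

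Genes called in both comparisons against vehicle were Dusp6 and Rbm3os. Dusp6 rose after FGF23 and fell in KL null, and it did so in all 6 ways of giving each comparison its own 2 vehicle arrays. Rbm3os, a dim transcript at 4.20 ± 0.10 with vehicle, 4.80 ± 0.18 with FGF23 and 4.59 ± 0.14 in KL null, was higher in both, but in 0 of the 6 splits. Independent lists of these sizes would share 0.746 genes in opposite directions and 0.617 in the same direction. Simulated unchanged groups with shared controls shared 0 and 0.05. With no gene changed in them, few calls are possible, so they are no benchmark for lists of these sizes. Across genes, which are not independent replicates, the log2 folds of both comparisons correlated at 0.24, against 0.499 in simulated unchanged groups and -0.0434 to 0.142 with split controls. Their covariance was 0.0106 against 0.00691 simulated, a difference of 0.00374, and -0.00237 to 0.00672 with split controls. The simulated groups carried neither the differences in array spread nor the correlation of same-numbered FGF23 and KL null arrays. The difference can therefore not be read as a shared response. Rbm3os lost its FGF23 call in 10 of the 12 fits without 1 array, all but those without WT FGF23 replicate 4 and KL null replicate 2 (highest adjusted p = 0.175, without WT FGF23 replicate 2), and its KL null call without WT vehicle replicates 1, 2 and 4 and KL null replicates 2 to 4 (highest 0.0944, without KL null replicate 2). Over all alternatives the adjusted p ran from 0.0344 to 0.512 and from 0.0206 to 0.114.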

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

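The tests of the proximal tubule pattern below were chosen after the result was seen.

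Among the genes named in the report, 13 single values stood far from the 3 other arrays of their group, where chance alone would give 16 among 312 groups of 4 arrays. In KL null replicate 1 these were Acsm2 at 11.76 (others 11.55 to 11.57), Cyp2e1 at 10.79 (11.42 to 11.52), Gatm at 11.62 (11.14 to 11.19), Nfkbia at 8.05 (8.85 to 8.90) and Podxl at 9.21 (9.48 to 9.52). In WT vehicle replicate 4 they were Hadhb at 11.33 (11.05 to 11.09), Kcnj16 at 11.40 (11.20 to 11.23) and Slc22a26 at 6.09 (8.55 to 8.98). The others were Fbp1 at 12.47 in KL null replicate 2 (12.33 to 12.35), Rbm3os at 4.80 in the same array (4.50 to 4.55), Oxsr1 at 9.32 in KL null replicate 3 (9.47 to 9.49), Tmem140 at 8.35 in KL null replicate 4 (8.76 to 8.79) and Gatm at 12.12 in WT FGF23 replicate 3 (12.14 in the other 3).

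Outside the genes analysed, 7064 of the 28853 probe sets had no gene symbol or several. Tested together with all the others, 237 of these differed between KL null and wild type with vehicle, 153 higher and 84 lower, a signal that the report does not cover.

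Proximal tubule markers were lower in KL null kidneys, with 13 of 24 called lower and a median log2 fold of -0.35 (adjusted p = 3.52e-08). A lower share of proximal tubule cells in the KL null samples would raise the markers of every other cell type. The median fold was below 0 in 4 of the other 4 structural lists, or 3 after a further quantile normalization. That count says little, since random lists matched to them on mean value had medians of -0.0438 to -0.005. The podocyte median lay at percentile 0.07 of its random lists, which drew genes independently. Collecting duct, endothelial and thick ascending limb markers lay at 3.97, 6.58 and 65.2. Podocyte markers (median -0.26, SD over members 0.175) stayed called lower after that normalization (adjusted p = 0.00198) and without KL null replicates 1 and 2 (0.0434), though not with an estimated correlation (0.246). Of these lists, only the podocyte markers argue against such a share as the whole cause. Collecting duct markers had a median of -0.12 (SD 0.148), then -0.12 (SD 0.151) and -0.08 (SD 0.164) in those fits. Endothelial markers had -0.10 (SD 0.143), then -0.08 (SD 0.146) and -0.09 (SD 0.156). Both lost their calls (0.108 and 0.0602, then 0.219 and 0.281) as their mean t rose from -1.01 and -1.09 to between -0.984 and -0.553 and that of the other genes fell from 0.106 to between -0.0224 and -0.00741. Thick ascending limb and distal convoluted tubule markers (-0.02, then 0.00 and -0.03) were not called. Immune cell markers were higher (median 0.24, 22 of 24 positive), though not called with an estimated correlation (0.252), so that a larger share of immune cells stays open. Their members with a negative fold went from 2 to 6 after the further quantile normalization and to 9 without KL null replicates 1 and 2. The immune list stayed called higher in both fits (camera adjusted p = 0.00494 and 0.00279). Complement and lysosomal macrophage genes were higher too (median 0.61, adjusted p = 0.0812 with an estimated correlation). That list was written after values were seen and holds Gpnmb, already among the largest increases, so it adds no separate support. The narrower spread of KL null arrays 1 and 2 is argued against as well, since the proximal tubule list stayed called lower after that normalization and without those arrays, at adjusted p values of up to 3.58e-06. Lower expression of these genes per cell in the absence of klotho, and the strain label that goes with the genotype, stay open and untested, and the list was not called with an estimated correlation (0.173).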

How the results depend on the processing

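Fits without the arrays of lowest spread, with array spread as a covariate, or with the 2 groups and a block were chosen after seeing the data. In the alternatives with 1 value per gene, the splits of the vehicle arrays aside, no called gene was called in the opposite direction. Of the alternative tests of named genes, 2666 kept their direction and their side of the threshold, 176 lost a call, 42 gained 1 and 0 turned. Of those of lists, 1085 kept both, 127 lost a call, 15 gained 1, 65 changed direction without a call and 6 turned between a call and the other direction. For FGF23 against vehicle (17 genes) the count was 10 after a further quantile normalization, 6 with each array centred on its median, 6 with every probe set of 1 symbol and 5 with every table entry tested. It was 7 with only the 2 groups, 2 in an unmoderated model, 6 with the replicate block, 8 without WT FGF23 replicates 1 and 2, 9 without those of KL null too. It was 11 with array spread as a covariate, 11 with a fold of at least 1.5, and 4 to 14 without 1 array. Its called lists (14) became 5 after quantile normalization, 4 among genes above the median mean value, 7 without WT FGF23 replicates 1 and 2, 7 without those of KL null too. They were 9 with the covariate, 1 with an estimated correlation and 4 with fry, and 9 to 16 without 1 array. For KL null against wild type (1598 genes) the count was 2852 with array quality weights, 491 with a fold of at least 1.5 and 828 to 1728 without 1 array. The called lists (13) became 7 among genes above the median mean value, 0 with an estimated correlation and 10 to 14 without 1 array. The log2 fold of Kl ran from -0.9433 to -0.8467 without 1 array. FGF23 against KL null (2386) gave 944 without WT FGF23 replicates 1 and 2, 1166 without those of KL null too, 577 with a fold of at least 1.5 and 1218 to 2794 without 1 array. The 2 genes called in both comparisons became 1 under quantile normalization, centring, every probe set, every table entry, the unmoderated model, the block, the covariate, the fold limit, the fit without replicates 1 and 2 of both groups, and each of the 6 splits of the vehicle arrays. There were 4 with trend and robust moderation and 1 to 3 without 1 array. After FGF23 the list test turned for immune cell markers and chemokines without WT FGF23 replicates 1 and 2 (adjusted p = 0.0445) and without those of KL null too (0.0215), for thick ascending limb and distal convoluted tubule markers in the latter fit (0.993), and with the covariate for distal sodium and potassium transport (0.89), endothelial markers (0.00411) and fibrosis genes (0.000343). The fold limit removes genes by construction and leaving out arrays lowers their number; for the other settings the cause was not tested. Scanner files were not used here, so signal over background is not known, and low values such as those of Rbm3os cannot be told from background.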

Other observations

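The 8 gene lists in the next 2 paragraphs were written after values had been seen, some of their top genes among them, and the tests of array spread and of the 7 other lists against matched lists were also chosen after the result was seen.

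Of 14 complement and lysosomal macrophage genes 11 rose in KL null kidneys and 0 fell, 12 when adjusted over the list alone (median log2 fold 0.61, camera adjusted p = 4.46e-11 over the 8 lists, adjusted p = 0.0812 with an estimated correlation). Apoe, a lipoprotein made by macrophages, rose by 1.24 (adjusted p = 2.9e-05), the cathepsin gene Ctss by 1.58 (0.000486), Ms4a6c by 0.87 (0.000205), the complement genes C1qa, C1qb and C1qc by 0.61, 0.66 and 0.64, and Tyrobp by 0.61. The broadly expressed Ctsb and Ctsd did not pass (0.06 and -0.09), and neither did Laptm5 (0.43, adjusted p = 0.134). Organic anion and cation transporter genes had 6 of 15 lower and 1 higher, or 8 and 1 when adjusted over the list alone (median -0.27, camera adjusted p = 6.74e-05, adjusted p = 0.0732 with an estimated correlation). The organic anion transporter gene Slc17a3 fell by 1.49 (adjusted p = 5.4e-05), Slc22a13 by 1.03 (8.64e-05), Slc22a2 by 0.71 (0.000689) and Slc22a8 by 0.57 (0.0016), whereas Slco4c1 rose by 1.64 (0.00132). In the list of heat shock and cold-inducible genes 4 of 12 fell and 2 rose, or 7 and 2 when adjusted over the list alone (median -0.26, camera adjusted p = 0.0137, adjusted p = 0.413 with an estimated correlation). Hsph1 fell by 0.96 (adjusted p = 0.00269), Dnaja1 by 0.56 (0.0038), Hsp90aa1 by 0.39 (0.0137) and Hspa8 by 0.30 (0.0319). Rbm3 rose by 1.47 (2.2e-05) and Cirbp by 1.01 (0.004).

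Of 6 female-biased kidney genes 5 fell in KL null and 1 rose, likewise over the list alone. Among the 5, Akr1c18, Slc22a7 and Slc22a19 had been seen as top decreases before the list was written, so no test of the whole list is given. The other 3 members had a median of -0.74, with Slc7a12 (-0.98) and Slco1a6 (-0.74) lower and Cyp4a14 (0.66) higher. Of 12 male-biased genes 5 rose, among them Cyp4a12a (1.36) and Cyp2d9 (1.11), and 3 fell, Kap, Odc1 (-1.14) and Cyp4b1 (-0.75), also over the list alone. Sterol and fatty acid synthesis genes had 5 of 27 lower and 3 higher, or 7 and 3 over the list alone (median -0.05, camera adjusted p = 0.019, adjusted p = 0.57 with an estimated correlation), with Cyp51 (-1.68), the desaturase Scd1 (-1.65), Elovl6 (-0.80), Fasn (-0.76) and Me1 (-0.58) lower and Fdft1 (0.45) among those higher. Amino acid response genes (adjusted p = 0.621; Stc2 higher, Shmt2 lower) and Y-linked genes (0.64) were not called. After FGF23 0 members of these lists passed over all genes except Ddit3, which rose. The transporter (median -0.10, camera adjusted p = 0.00025), female-biased (-0.36, 0.00352) and male-biased lists (-0.11, 0.04) were called lower, with 2, 0 and 0 members lower over the list alone, but not with an estimated correlation (adjusted p = 0.155, 0.165 and 0.165 with an estimated correlation). The sterol (0.104), complement (0.312), amino acid (0.425), heat shock and Y-linked lists (both 0.592) were not called after FGF23.

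After FGF23, 8 gene lists were called lower with medians between -0.14 and -0.07 and 0 members called, and 0 of the 8 were called with an estimated correlation (adjusted p = 0.177 to 0.388). The proximal tubule and fatty acid oxidation lists were set apart because they stayed called lower without FGF23 arrays 1 and 2 (camera adjusted p = 0.00297 and 4.32e-06). That fit is therefore no test for these 2 lists. Their medians went from -0.14 (SD over members 0.0894) and -0.11 (SD 0.155) to -0.10 (SD 0.115) and -0.14 (SD 0.142) in it. With array spread as a covariate both were called lower (8.58e-05 and 0.00213). A further quantile normalization took the proximal tubule median to -0.08 (SD 0.0775) and ended its call (0.11), as it did for fatty acid oxidation (0.159). The fits disagree, so the narrower spread of FGF23 arrays 1 and 2 stays undecided for these 2 lists. For the other 6 lists it stays a candidate explanation: their medians went from between -0.11 and -0.07 (SD 0.108 to 0.176) to between -0.09 and -0.02 (SD 0.11 to 0.168) after that normalization, with 1 of them, interferon-stimulated genes (0.0242), still called lower. The correlation of fold with mean value went from -0.392 to -0.0614, and without those arrays 0 of the 6 were called, but the collecting duct median was -0.06 (SD 0.142) against -0.07 (SD 0.115), so its lost call (0.114), with a mean t of -0.453 against -0.877 before, does not count for array spread. A shift of abundant genes in general was tested with 10000 random lists matched on mean value. The proximal tubule median lay low among them, at percentile 0.16. The random lists drew genes independently, while the estimated correlation within the proximal tubule list was 0.119. Their spread is therefore too narrow for that percentile to decide. For 6 of the other 7 lists such a shift stays open, since their medians lay above the lowest 2.5% of theirs. A response to FGF23 stays open, not tested apart from these.

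In KL null kidneys 5 of 6 female-biased genes were lower and 5 of 12 male-biased genes higher, with 1 and 3 the other way. Male mice among the KL null samples are argued against, because the highest KL null array lay 0.17 below the highest wild-type array in the median of 3 Y-linked genes (difference -0.17), and Xist was between 11.06 and 11.41 in the 12 arrays. A loss of the female pattern of kidney expression stays open: of the genes not seen before, 2 of 3 female-biased (median -0.74) and 2 of 7 male-biased genes (median -0.05) moved as named. Together that is 40% (95% interval 12.2% to 73.8%, exact permutation p = 0.4). That share met the rule set before the test for counting against such a loss, but the interval is wide and the genes are too few to decide. The strain label is among the untested explanations.

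DNA of the other strain around Kl could give calls that do not depend on klotho. Of 29 measured neighbours, 25 before and 4 after Kl in the gene order of GRCm38.p6, 3 were called in KL null against 8.01% of all other genes (10.3%, odds ratio 1.33, 95% interval 0.257 to 4.33, Fisher exact p = 0.502): Hmgb1 (-0.56), Hsph1 (-0.96) and Brca2 (0.78). The interval is too wide to decide. Lower SREBP-regulated synthesis as a group was a further hypothesis for Cyp51, Scd1 and Fasn. With those left out, 50% of the members (12 of 24, 95% interval 29.1% to 70.9%) had a fold below 0. The remaining list was not called by camera, at an unadjusted p of 0.469. A share of at most 50% had been set before the test to count against the hypothesis, and this share met it. The interval is wide, however, and leaves a change of the whole pathway open.

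Counts were compared with other splits of the same arrays. For FGF23 against vehicle, 2 of 35 splits, the real one included, gave 17 or more genes, so chance is not excluded for that count. The other gave 31 genes and parts WT FGF23 replicates 1 and 2 with WT vehicle replicates 2 and 4, the 2 arrays of lower spread in each group, from the rest, which points to a structure of the samples. It shared 0 genes with the 17 and its smallest adjusted p was 0.00382, against 1.55e-08 for Egr1, and with array spread as a covariate the real split gave 11 genes. For called lists, 3 of 35 splits gave 14 or more, the highest other also 14, so chance is not excluded there either. For KL null against wild type 1 of 35 splits reached 1598 genes (highest other 2) and 1 of 35 reached 13 lists (highest other 11). This is the smallest share that 35 splits can give, 2.86%. The gene count stood far above that of every other split. The list count did not, and 0 of the 13 lists were called with an estimated correlation, so chance is not excluded for the number of lists. For FGF23 against KL null 1 of 35 reached 2386 genes (highest other 1), but those 35 take no account of the same-numbered pairs. The 8 splits that part all 4 pairs are too few for a share under 5%, and the 7 others gave 0 or 1 genes. For genes called in both comparisons, 1 of 100 splits of the 12 arrays reached 2 (highest other 1). That does not exclude a chance overlap, since independent lists of the observed sizes would share 0.746 genes in opposite directions and 0.617 in the same direction, against 1 and 1 observed.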
